A study of Mus musculus with 2 samples.

How the data were processed

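Whole cerebella of embryos at E16.5 were digested with papain and DNase, and dead cells were removed by sorting with 7-AAD, per the labels' protocols. For each genotype 3 samples were pooled, and 40000 cells of each pool were loaded for a 10x Genomics 3' v3.1 library. The deposited files hold whole-number UMI counts per gene and barcode for 1 control and 1 mutant library, not normalized, made by the authors with Cell Ranger 7.0.1 on the mm10 genome, per the submitters' processing notes. Whether reads in introns were counted, the annotation release and the way barcodes were called as cells are not given in the sources used here. The smallest barcode held 500 UMIs in both libraries. Of 32285 gene identifiers, 32235 were found in GENCODE M21 (GRCm38), which was used for coordinates. The groups were taken from the genotype labels.

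Cells were kept with at least 1000 UMIs, at least 500 detected genes and at most 10% mitochondrial UMIs, which 16812 of 21457 control and 16482 of 21596 mutant barcodes passed. Of the barcodes left out, 3400 of 4645 in the control and 3646 of 5114 in the mutant library had over 50% haemoglobin UMIs. Doublets were called in each library with Scrublet in scanpy at an expected rate of 16% and its automatic threshold, and 933 control cells (5.55%) and 827 mutant cells (5.02%) were removed. The remaining 31534 cells were scaled to 10000 UMIs and log-transformed, and 2000 variable genes ranked within each library entered 30 principal components, 15 neighbours and Leiden clustering at resolution 1, with no integration of the libraries. The 297 genes of the lists compared between genotypes were left out of the clustering, as were mitochondrial, ribosomal, haemoglobin and sex-linked genes.

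The 43 clusters were named from markers of 20 cell types. A marker counted as enriched in a cluster at a log2 ratio of at least 1 over the other cells and detection in at least 10% of the cluster, and a name needed at least 3 enriched markers that were also no fewer than 50% of the type's markers. The markers were fixed in advance, and these thresholds were not. Clusters stayed unnamed where the top 10 genes held more markers of another type, where at least 2 genes of motile cilia led a progenitor-like cluster, where all libraries' cells had a median depth below their library's median divided by 3 with no marker among the top 10 genes, or where Tfap2d had a log2 ratio of at least 2 in a cluster named for glutamatergic nuclei. The rules on cilia and Tfap2d were set after the data were seen. In all 27 clusters were named and 16 were not. No cluster passed as Purkinje cell, cerebellar nuclei, ependymal or midbrain neuron, so these types were not compared. At Leiden resolution 0.5 no cluster passed as PTF1A-lineage progenitor, so that setting gave no value for it.

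Expression was compared on UMIs summed over cells, as CPM, with the ratio taken as log2 of mutant plus 1 CPM over control plus 1 CPM. Genes entered at 10 CPM or more in either library. With 1 library per genotype no test, p-value or standard error was computed. Sums of UMIs carry exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals at 95%, ratios of UMI counts come from the exact conditional binomial, and list medians from 1000 Poisson redraws. A count of 0 allows up to 3 counts. List medians were placed among 10000 random lists of the same size matched in 20 bins of mean expression. A list member was called higher or lower at 1.5-fold with its counting interval on 1 side of 1. Per-cell readouts used cells thinned to 3000 UMIs. The Wnt readout required at least 2 UMIs of Axin2, Lef1, Nkd1, Notum, Sp5, Apcdd1, Wif1, Rnf43, Znrf3 and Tcf7 together, and the cycling readout 1 UMI of Mki67 or Top2a. Sex was marked by Xist and by 4 Y-linked genes.

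The design, the 17 gene lists, the markers and the rule for named genes were fixed before the data were examined. The rule took the 12 largest log2 ratios each way among genes at 50 CPM or more in the higher library, for the whole library, for the progenitor-like class and for the mutant-dominated clusters against control progenitor-like cells, and the 3 largest each way in other classes with at least 200 cells in each library. Gm-numbered, Rik, mitochondrial, ribosomal, haemoglobin and sex-linked genes were left out of the ranking. From each list the members with the largest difference were named, and Smarca4 and Ctnnb1 always. Mutant-dominated clusters were those with a share of the mutant library at least 5 times that of the control library. Genes of cluster 5 alone were named with the same rule, after the data were seen.

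The steps from summed UMIs to folds, intervals and list percentiles were tested on simulated Poisson counts in which 200 genes were changed. Clustering and naming were not part of this. The intervals assume Poisson counts, so coverage near 95% was built in and says nothing about the real spread. For the whole library, over 9346 genes, genes made 4-fold and 2-fold different were recovered at median folds of 3.98 and 1.99, and intervals held 94.9% of the unchanged genes. A second run stood for the depth of the progenitor-like class. It was scaled down from the same control library and used no sums of that class. There, over 9418 genes, the values were 3.96, 2.02 and 95.5%. In neither did an unchanged gene reach 2-fold, and of 100 random lists 5 and 3 lay outside the central 95% of matched lists.

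Alternatives were no or a stricter cell filter (2000 UMIs, 1000 genes, 5% mitochondrial), doublets kept, Leiden resolutions of 0.5 and 2, list genes kept in the clustering, classes transferred from control cells by their 15 nearest control neighbours, thinning to 1500 UMIs or none, 1 or 3 Wnt UMIs, no filter on low counts or 50 CPM, pseudocounts of 0.1 and 10, median-of-ratios scaling, means of per-cell CPM and 2 UMIs for sex marks. Others were added after the data were seen. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.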

Results

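The cerebella of mouse embryos at E16.5 were profiled by droplet-based single-cell RNA sequencing of transcript 3' ends, with unique molecular identifiers (UMIs) marking single captured molecules. The control animals lacked cre. The mutants carried Blbp-cre, which is active in radial glia and other neural progenitors, with a floxed exon 3 on 1 Ctnnb1 allele and floxed Smarca4 on both alleles, and they had lesions in the cerebellum. Deletion of exon 3 stabilises beta-catenin, the effector of canonical Wnt signalling, and Smarca4 encodes an ATPase of the BAF (SWI/SNF) chromatin remodelling complex. For each genotype 3 samples were pooled into 1 library, so there was 1 control and 1 mutant library and no replicate. The control library held 21457 barcodes with 2.26e+08 UMIs and the mutant library 21596 barcodes with 2.21e+08 UMIs. After filtering, 15879 control and 15655 mutant cells were kept, with a median of 9994 and 9660 UMIs and of 3306 and 3268 detected genes. Haemoglobin transcripts made up 7.56% of the UMIs of kept control cells and 8.80% of those of kept mutant cells. All intervals below are 95% intervals, exact for counts and shares and from redrawn counts for list medians, and cover counting error only, not the spread between animals, and no difference was tested.

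The first question was whether the 2 targeted genes differed between the libraries. Smarca4 (ENSMUSG00000032187, GRCm38 chromosome 9, 21616169 to 21704230, plus strand) was lower in the mutant library, at 49.3 CPM (UMIs of the gene scaled to equal library totals; interval 48.3 to 50.4) against 68.1 (66.9 to 69.3), a mutant to control ratio of 0.725 (0.704 to 0.745). Ctnnb1 (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507, plus strand) was higher, at 172 CPM against 118 CPM, a ratio of 1.45 (1.43 to 1.48). In progenitor-like cells Ctnnb1 was lower in the mutant library, at 161 against 182 CPM, with a ratio of 0.888 (0.845 to 0.932), and in cluster 5 the ratio was 1.05 (0.970 to 1.14). In oligodendrocyte precursor-like cells Smarca4 stood at 37.4 CPM in the mutant and 66.5 CPM in the control library, and in brainstem neuron-like cells at 31.6 and 83.8 CPM. In cluster 5, the progenitor-like cluster that held many cells of both libraries, Smarca4 was 36.2 CPM in mutant and 37.5 CPM in control cells. In endothelial-like cells, outside the cre lineage, the ratio was 0.854 (0.640 to 1.14), in pericyte- or mural-like cells 0.939 (0.707 to 1.25) and in fibroblast-like cells 0.854 (0.684 to 1.07). Exon 3 of Ctnnb1 (chromosome 9, 120950522 to 120950749, 228 bases) lies 3095 or 2368 transcript bases from the 3' end in 2 annotated transcripts of 15 exons. A 3' tag lies outside that exon, so the Ctnnb1 level checked nothing about its deletion, and which exons of Smarca4 were floxed is not given in the sources used here.

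The second question was how the cellular make-up of the cerebellum differed. The mutant library held far fewer PAX2-type GABAergic interneuron-like cells and PTF1A-lineage progenitor-like cells, fewer cells of the granule lineage, fewer unipolar brush cell-like and oligodendrocyte precursor-like cells, and a larger share of choroid plexus epithelium-like cells. GABAergic interneuron-like cells, marked by Pax2, Slc32a1 and Slc6a5, were 3.38% of control cells (537 cells) and 0.0639% of mutant cells (10 cells), a mutant to control ratio of 0.0189 (0.00901 to 0.0350). PTF1A-lineage GABAergic progenitor-like cells, the ventricular zone progenitors of cerebellar inhibitory neurons, were 2.39% of control cells (380 cells) and 0.0383% of mutant cells (6 cells), a ratio of 0.0160 (0.00584 to 0.0352). Other cells with GABAergic genes were not few: unnamed cluster 12, with Gad2 and Pnoc among its leading genes, held 1.57% of control and 4.10% of mutant cells. Cluster 12 had the midbrain or isthmic neuron markers Pax7, Tal2, Gata3, Pou4f1 and Sox14 enriched. It lost that name only by the rule on the top 10 genes, so its cells need not belong to the cerebellar GABAergic lineage. Granule cell precursor-like cells were 13.1% and 2.84%, and differentiating granule neuron-like cells 11.6% and 2.52%. Together this granule lineage had a ratio of 0.217 (0.201 to 0.233). Unipolar brush cell-like cells, excitatory interneurons of the rhombic lip, were 16.6% of control and 6.20% of mutant cells, with a ratio of 0.373 (0.346 to 0.401). Oligodendrocyte precursor-like cells were 2.50% and 0.856% (ratio 0.342), and brainstem neuron-like cells, marked by Hox genes, 2.31% and 0.358%. Choroid plexus epithelium-like cells were 1.38% of control and 2.95% of mutant cells, a ratio of 2.14 (1.82 to 2.52). These are shares of whole libraries: all cells outside the mutant-dominated clusters described below had a ratio of 0.438 (0.425 to 0.450), close above the values of unipolar brush cell-like and oligodendrocyte precursor-like cells.

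Classes outside the neural lineage had shares of the whole libraries that were closer to each other, and so ratios above the 0.438 of all cells outside the mutant-dominated clusters, except for neural crest- or Schwann-like cells (0.225, 0.110 to 0.427). Endothelial-like cells were 1.19% of control and 1.33% of mutant cells, fibroblast- or meninges-like cells 3.40% and 3.53%, pericyte- or mural-like cells 2.42% and 2.34%, microglia- or macrophage-like cells 1.08% and 0.850%, and erythroid-like cells 1.47% and 2.21%. Roof plate- or rhombic lip-like cells were 1.20% and 1.27%, and neural crest- or Schwann-like cells 0.340% and 0.0767%. Chemokine genes were among the leading genes of the microglia-like clusters 37 (Ccl2, Ccl7) and 38 (Ccl4, Ccl3), and histone genes of S phase led unipolar brush cell-like cluster 9. Neural progenitor- or astroglial-like cells were 10.8% of control and 10.0% of mutant cells. No direction is given for this class, because its mutant to control ratio lay between 0.530 and 1.72 over the alternative settings, on both sides of 1. 3 clusters were kept out of named classes by rules set after the data were seen. Cluster 25, led by genes of motile cilia, held 2.13% of control and 1.29% of mutant cells. Clusters 3 and 21, in which Tfap2d of the dorsal midbrain was enriched, held 0.819% and 1.53% of control and 8.57% and 2.52% of mutant cells. With classes transferred from control cells alone the ratio was 0.304 for GABAergic interneuron-like cells, 0.640 for the granule lineage and 0.563 for unipolar brush cell-like cells, all nearer to 1. The low share of PTF1A-lineage cells depended on 2 settings. With no cell filter the ratio was 2.17, because a mutant cluster in which neither Ptf1a nor Kirrel2 was enriched took that name, and with classes transferred from control cells alone it was 1.19. At Leiden resolution 0.5 no cluster took the name, and 917 control and 16 mutant cells formed 1 GABAergic interneuron-like cluster.

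**Figure D1:**
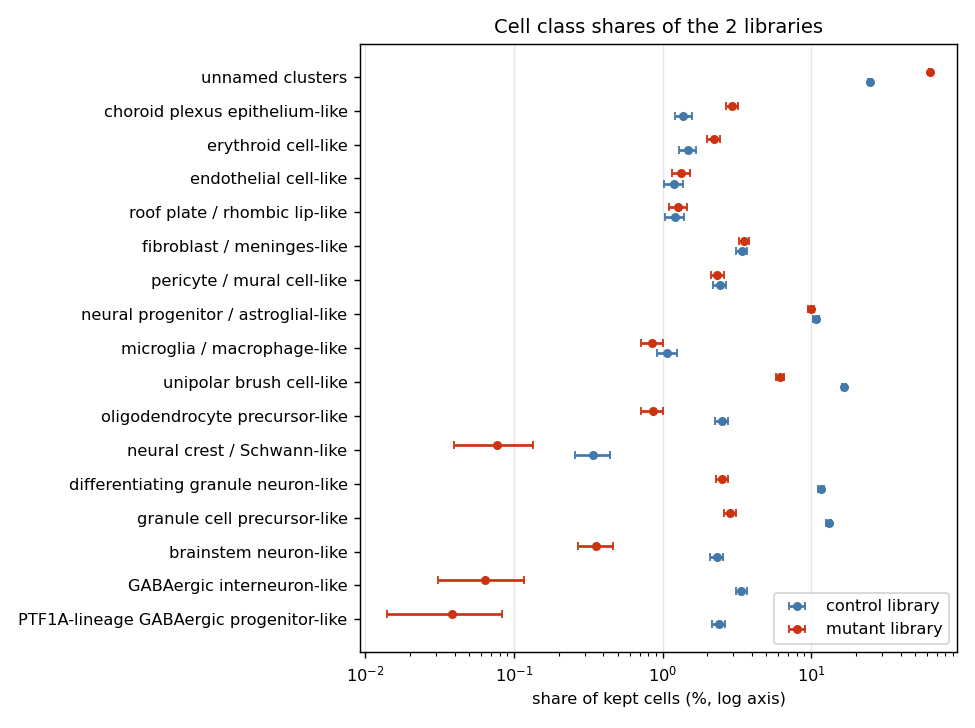
Share of kept cells in each class (horizontal log axis, percent) in the control library (blue) and the mutant library (red), with exact binomial 95% intervals as bars; the classes are ordered by the mutant to control ratio. GABAergic interneuron-like cells lie at 3.38% and 0.0639%, and choroid plexus epithelium-like cells at 1.38% and 2.95%.

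With the cell filter used, most of the mutant library lay in clusters with a far smaller share of the control library. With no cell filter the share of the mutant library in such clusters was 39.8%. Of 43 clusters, 11 had a share of the mutant library at least 5 times their share of the control library, and these mutant-dominated clusters held 8886 mutant cells, 56.8% (56.0 to 57.5), against 191 control cells, 1.20% (1.04 to 1.38). Of these control cells, 130 lay in cluster 3, 38 in cluster 32 and 12 in cluster 41, so these clusters were not absent from the control library. Clusters 4, 13, 35 and 39 held 1443, 843, 294 and 115 mutant cells and 0 control cells. The exact interval allows a control share of up to 0.0232% for each, and the allowance of 3 counts up to 0.0189%. Clusters 17 and 32 passed as neural progenitor- or astroglial-like and cluster 41 as fibroblast- or meninges-like, and the other 8 carried no class name. With 1 library per genotype, a cluster made up mostly of 1 library may reflect that library and not a cell type.

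The third question was which cells carried a transcriptional readout of Wnt signalling. Counted over 10 target genes with each cell thinned to 3000 UMIs, 26.2% (25.4 to 26.9) of control cells and 58.7% (57.9 to 59.6) of mutant cells had at least 2 target UMIs. Thinning left out 2386 control and 2014 mutant cells of lower depth; the unthinned shares were 60.8% and 76.7%. Within the mutant library the share was 76.7% in the mutant-dominated clusters and 34.2% in the others, against 26.3% in the same other clusters of the control library. Of the 11 mutant-dominated clusters, 8 had shares from 78.8% (cluster 17) to 100% (cluster 39), while cluster 3 had 12.02%, cluster 32 had 22.1% and fibroblast-like cluster 41 had 3.39%. Cluster 34, outside the mutant-dominated set, held 84.3% positive cells of the mutant and 16.9% of the control library. In cluster 5 the shares were 26.6% of mutant and 15.8% of control cells, in roof plate- or rhombic lip-like cells 43.9% and 17.8%, and in oligodendrocyte precursor-like cells 34.2% and 16.3%.

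Background was read in cells that should lack these transcripts. Erythroid-like cells were positive in 0 of 229 control cells and in 5.17% of mutant cells, at median depths of 19133 and 18275 UMIs, and microglia-like cells in 3.15% and 19.2%, at 9825 and 10891 UMIs. Without thinning the shares were 3.42% of control and 25.7% of mutant erythroid-like cells, and 12.9% and 37.6% of microglia-like cells. The erythroid-like background was thus not small at full depth. After thinning, mutant shares in shared classes at or below 19.2% are therefore not read as expression, and the mutant background was above the control background. A share above 19.2% does not by itself show expression. The microglia-like share came from 99 mutant cells, with an interval reaching 28.3%. Its rise over the control share was larger than that of cluster 5 (15.8% to 26.6%). It was close to that of oligodendrocyte precursor-like cells and below that of roof plate- or rhombic lip-like cells. For cluster 5 this readout therefore cannot separate expression from background. Endothelial-like cells had 70.8% positive in the control and 66.3% in the mutant library, and all 5 non-neural classes together 31.2% and 29.4%.

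**Figure D2:**
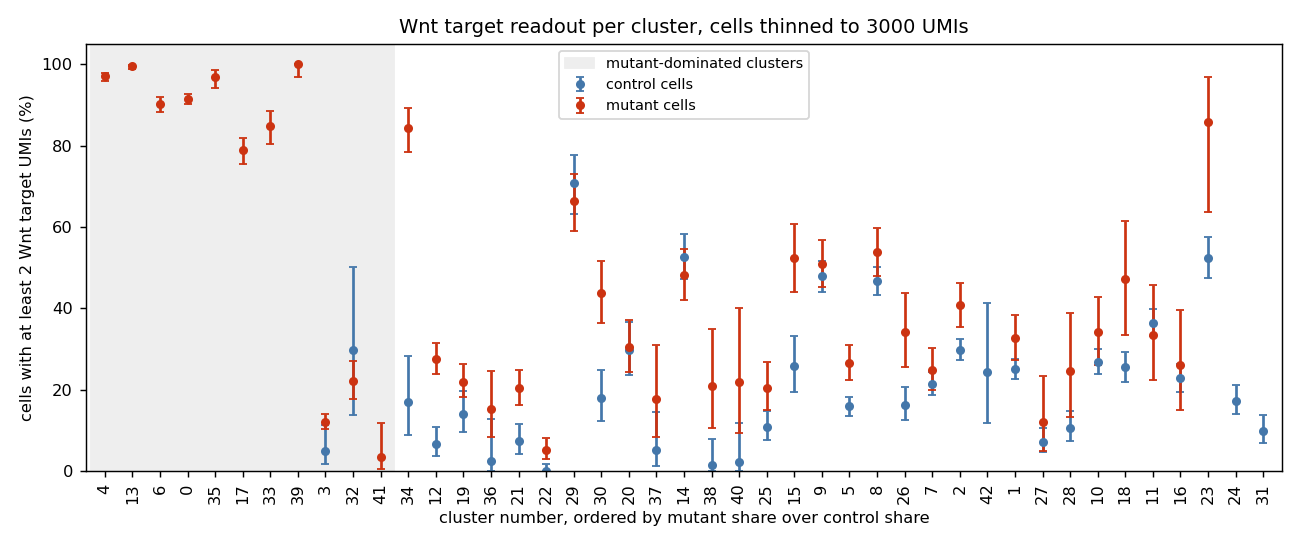
Percent of cells with at least 2 UMIs of 10 Wnt target genes after thinning to 3000 UMIs (vertical axis) in each cluster (horizontal axis, ordered by mutant over control share), for control cells (blue) and mutant cells (red), with exact binomial 95% intervals as bars and the mutant-dominated clusters shaded. In the shaded part 8 clusters lie between 78.8% and 100%, and clusters 3, 32 and 41 lie at 12.02%, 22.1% and 3.39%.

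Summed over all kept cells, the mutant library was marked by high levels of Wnt target genes and low levels of cell cycle genes. Among 9789 genes at 10 CPM or more in either library, 408 were at least 2-fold higher and 202 at least 2-fold lower in the mutant library by size alone. The highest log2 ratio was that of Wif1, a secreted Wnt inhibitor, at 299.5 CPM in the mutant and 2.37 CPM in the control library. Fstl4 was 546 and 5.48 CPM, Adamts19 200.2 and 5.63 CPM, Notum, a secreted Wnt-inactivating enzyme, 53.4 and 0.993 CPM, and Rgs6 298 and 10.1 CPM. Hpse2, Pde1a, Cyp1b1, Cygb, Tmem132c, Shox2 and Tnfrsf19 completed the 12 highest. Among the lowest were Crabp1 (8.73 against 70.7 CPM), Mfap4, a granule cell precursor gene (25.3 against 173 CPM), Tlx3 (11.2 against 70.1 CPM), Pde1c (71.5 against 332 CPM) and Nhlh2, a transcription factor of differentiating granule neurons (16.2 against 69.7 CPM), with Ppp2r2c, Btbd11, Spsb4, Uncx, Ppp1r14c, Adarb2 and Cadps2.

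Of 14 measured Wnt/beta-catenin targets, 12 were higher and 0 lower by at least 1.5-fold, with a median log2 ratio of 2.45 (2.40 to 2.50), at percentile 100 among 10000 random lists matched on expression, as a description of these libraries. Lef1 was 166 and 21.9 CPM and Axin2 112 and 18.3 CPM. All 4 measured genes of a WNT medulloblastoma class list were higher (median 2.19), among them Gad1 (56.0 against 13.1 CPM), the GABA-synthesising enzyme, although GABAergic interneuron-like cells were few. Of 10 cell cycle inhibitors 4 were higher and 0 lower: Cdkn2b (15.7 against 1.22 CPM), Cdkn1a (114 against 23.5 CPM), Gadd45g (170.2 against 67.4 CPM) and Cdkn1c (339 against 151 CPM). Among 25 BAF subunits 3 were higher and 0 lower, with a median of 0.18: Brd7 (292 against 87.8 CPM), Dpf1 and Smarcd3. Smarca4 itself, a member of that list, did not reach the 1.5-fold size. Of 4 mid-hindbrain patterning genes 1 was higher, Gbx2 (25.0 against 2.85 CPM), with a median of 0.42. Of 12 neural stem cell transcription factors 2 were higher, Id4 and Id3, and 3 lower, Pax6 (69.7 against 238 CPM), Nfia and Nfib, with a median of 0.04.

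Of 15 neuronal cytoskeleton genes 5 were lower, among them Nefm (25.2 against 68.0 CPM), Nefl and Gap43, with a median of 0.06. Of 7 Hedgehog pathway genes 1 was lower, Mycn (21.3 against 37.4 CPM; median −0.23), and of 9 Notch pathway genes 2 were lower, Hey1 and Dll3 (median −0.07). Of 8 p53 targets 1 was higher, Cdkn1a (median 0.26). Of 11 extracellular matrix genes 1 was higher and 1 lower (median −0.02), and of 13 hypoxia and glycolysis genes 1 was lower (median −0.02). None of 24 actin cytoskeleton genes (median −0.12), 12 immediate early and dissociation genes (0.16) or 2 interferon response genes (0.03) reached the 1.5-fold size. With the mutant-dominated clusters left out of both libraries, the Wnt median was 0.76.

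The fourth question was proliferation, since the lesions are described as proliferative in the labels. Cell cycle transcripts were lower in the mutant library. Of 53 measured G2/M genes 37 were lower and 0 higher, with a median log2 ratio of −0.64 (−0.66 to −0.62, percentile 0), for example Cks2 (95.3 against 193 CPM), Birc5 (68.1 against 132 CPM) and Cenpa (65.8 against 126 CPM). Of 41 S phase genes 14 were lower and 0 higher (median −0.48), led by Tyms, the thymidylate synthase (35.7 against 70.7 CPM), and Rad51ap1 (13.2 against 26.4 CPM). Cells with a UMI of Mki67 or Top2a, after thinning to 3000 UMIs, were 25.6% (24.9 to 26.4) of control and 14.8% (14.2 to 15.4) of mutant cells, and 37.1% and 23.7% without thinning. The mutant share was 11.9% in the mutant-dominated clusters and 18.8% in the others, but 95.8% in the mutant-dominated cluster 35, which held 294 cells. In the same other clusters of the control library it was 25.8%. Within shared classes the shares were closer, with 21.2% of control and 21.4% of mutant granule cell precursor-like cells, 23.3% and 24.3% of oligodendrocyte precursor-like cells, and 35.5% and 39.9% of unipolar brush cell-like cells. G2/M medians were less alike: in oligodendrocyte precursor-like cells 27 of 53 genes were higher and 0 lower (0.59), and in endothelial-like cells 25 of 45 were lower and 0 higher (−0.80). The share of endothelial-like cells with Mki67 or Top2a was nonetheless 9.94% in control and 9.78% in mutant cells. Differentiating granule neuron-like cells, which have left the cell cycle, gave a background of 6.82% and 4.08% at median depths of 10238.5 and 10038 UMIs.

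Within neural progenitor- or astroglial-like cells, Wnt targets were higher in the mutant library. This class held 1715 control and 1571 mutant cells, but the control cells lay in clusters 5 and 18 and the mutant cells in clusters 17, 5 and 32. Of 12 measured Wnt targets 10 were higher and 0 lower, with a median log2 ratio of 2.28 (2.19 to 2.40), including Notum (58.6 against 0.209 CPM), Lef1, a transcription factor that binds beta-catenin (132 against 4.85 CPM), and Sp5 (58.8 against 5.68 CPM). Of 9791 genes 271 were at least 2-fold higher and 195 lower. Plppr5, Spock1, Pcdh15, Olfm3, Pde1a, Wif1, Mybpc1, Tmem132c and Fst were also among the 12 highest. Among the 12 lowest were Gria1 at 9.32 against 106 CPM, Gria4 at 51.6 against 310.1 CPM and Gabrb1 at 66.1 against 418 CPM, together with Mgll, Adarb2, Cntn1, March3, Slc24a3, Pla2g7, Sdc3 and Myo16. Of 14 neuronal cytoskeleton genes 9 were higher (median 0.85), among them Tubb3 (162 against 49.2 CPM) and Dcx, and of 9 extracellular matrix genes 6 were lower (median −0.66), among them Sparc (311 against 632 CPM) and Col4a1. The G2/M median was 0.07, and its sign reversed in 6 of 14 alternative settings, so no direction is given for it.

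In cluster 5 alone, with 1006 control and 428 mutant cells, the difference was smaller. Of 9429 genes 61 were at least 2-fold higher and 62 lower, and of 11 Wnt targets 8 were higher and 0 lower (median 1.35). Ccnd1, the cyclin D1 gene, was 77.0 against 23.9 CPM, Tnfrsf19 76.0 against 18.8 CPM and Nkd1 65.8 against 25.2 CPM. Of 39 S phase genes 11 were higher (median 0.42) and of 51 G2/M genes 6 were higher (median 0.29), while the share of cells with Mki67 or Top2a was 15.4% in control and 15.6% in mutant cells. Of 11 neuronal cytoskeleton genes measured in this cluster 0 were higher and 2 lower. Mgll had a log2 ratio of −2.88, and Gabrb1 stood at 52.2 against 245 CPM. Over the alternative settings for the progenitor-like class, this cluster alone among them, the number of genes 2-fold apart ranged from 123 to 962 and the Wnt median from 0.95 to 3.22.

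Set against control progenitor-like cells, the mutant-dominated clusters, summed, had higher Wnt targets and neuronal cytoskeleton genes and lower Notch and stem cell genes. The sum mixes clusters of different kinds, so these need not go together within a cell. Sox2, Sox9, Hes1, Hes5 and Id4, members of the Notch or stem cell lists, were also among the markers that named the reference class. Lower values of these genes were therefore partly set by the choice of reference. Of 13 Wnt targets 12 were higher and 0 lower, with a median log2 ratio of 3.96 (3.65 to 4.18), including Nkd1 (711 against 33.9 CPM) and Axin2 (170.1 against 20.0 CPM). Of 15 neuronal cytoskeleton genes 12 were higher and 0 lower (median 2.89), with Tubb3 at 1035 against 49.2 CPM and Stmn2 at 779 against 87.6 CPM. Of 10 Notch pathway genes 8 were lower and 1 higher (median −1.82), with Hes5 at 104 against 504 CPM and Notch1 at 26.1 against 104 CPM. Of 13 neural stem cell transcription factors 10 were lower and 0 higher (median −1.50), with Sox2 at 159 against 446 CPM and Sox9 at 96.5 against 361 CPM. Against the other mutant cells the differences were smaller: the median of this list was 0.08, with 1 of 12 higher and 2 lower, that of neuronal cytoskeleton genes 0.45, with 5 of 15 higher and 2 lower, and that of Notch pathway genes −0.42, with 4 of 10 lower and 1 higher. Of 13 immediate early and dissociation genes 10 were lower (median −1.30; −1.47 against the other mutant cells) and of 14 hypoxia and glycolysis genes 9 (median −0.82), lists that can move with handling. Of 9 extracellular matrix genes 7 were lower (median −1.04), and of 25 BAF subunits 14 were higher and 1 lower (median 0.59), led by Actl6b, a subunit of the neuronal complex (68.7 against 2.76 CPM), and Brd7 (429 against 92.2 CPM). Of 52 G2/M genes 20 were lower and 3 higher (median −0.44). Cdkn1a was 177 against 5.63 CPM.

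Of 10214 genes in this comparison 1029 were at least 2-fold higher and 1256 lower. The 12 highest were Fstl4 (936 against 1.20 CPM), Notum, Shox2, Pcdh15, Tfap2d, Ndst4, Myt1l, a neuronal transcription factor (631 against 10.6 CPM), Wif1, Cygb, Tmem132d, Sst and Pcsk2. Tfap2d, Ndst4 and Sst were leading genes of cluster 3, which held 1342 of the 8886 mutant cells. Among the 12 lowest were Olig1, Slc6a11, the water channel gene Aqp4 (4.12 against 237 CPM), Aldoc, Scrg1, Timp4, Apoe (166 against 5152 CPM), Tril, Rlbp1, Metrn and Dbx2. Genes outside the lists took part in the clustering and so help to define these clusters, whereas list members did not. The list members Sox2, Sox9, Hes1, Hes5 and Id4 did, however, help to name the control progenitor-like class. Smarca4 was 51.3 CPM in the mutant-dominated clusters and 43.0 CPM in control progenitor-like cells, and Ctnnb1 209.6 and 182 CPM. Against the other cells of the mutant library, Ctnnb1 was 209.6 against 125 CPM.

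**Figure D3:**
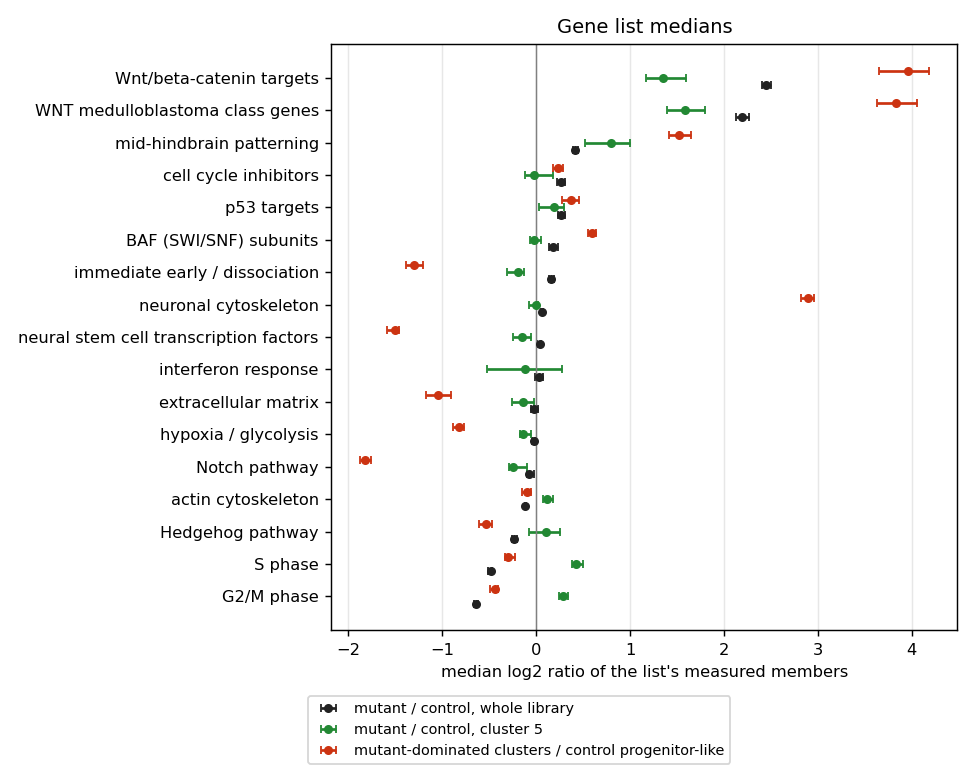
Median log2 ratio of the measured members of each gene list (horizontal axis) for the mutant over the control library (black), mutant over control cells of cluster 5 (green) and the mutant-dominated clusters over control progenitor-like cells (red), with 95% counting intervals as bars. Wnt/beta-catenin targets lie at 2.45, 1.35 and 3.96, and Notch pathway genes at −0.07, −0.25 and −1.82.

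Each pool held cells of embryos of both sexes, which gave a look at more than 1 embryo within a library. Cells with Xist and no Y-linked UMI made up 33.5% of control and 28.0% of mutant cells, and cells with Y-linked UMIs and no Xist 42.4% and 46.4%. In the mutant pool the mutant-dominated clusters held 60.2% (58.7 to 61.6) of Xist-marked and 58.3% (57.1 to 59.4) of Y-marked cells. Granule lineage-like cells were 18.9% of Xist-marked and 27.8% of Y-marked control cells, and 6.26% and 4.75% of mutant cells. Brainstem neuron-like cells were 4.60% of Xist-marked and 0.891% of Y-marked control cells, and 0.411% and 0.303% of mutant cells, so the size of their difference depended on the embryos of the control pool. Cells with both marks were 9.35% of control and 8.26% of mutant cells, which can be doublets or carry free RNA.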

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

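Barcodes left out by the cell filter also held Wnt target transcripts, at 103 CPM (99.9 to 107) in 5114 mutant and 25.1 (23.4 to 26.9) in 4645 control barcodes. Of these barcodes 3646 and 3400 had over 50% haemoglobin UMIs. Free RNA in the mutant library therefore had to be weighed for classes shared by both libraries, and of the tests below only the one of cluster 5 against microglia-like cells was chosen before the result was seen.

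If free RNA from the mutant-dominated clusters made the Wnt excess of shared classes, the excess per excess UMI of Fstl4, Pcdh15, Rgs6 and Adamts19 should equal that of background cells. In cluster 5 it was 3.53 (2.83 to 4.49) times that of microglia-like and 1.48 (1.12 to 1.94) times that of erythroid-like cells. Both lower bounds were above 1, the outcome set as speaking against free RNA alone. The Wnt excess itself was 276 CPM in cluster 5, 280 CPM in microglia-like and 66.9 CPM in erythroid-like cells. The excess of the 4 other genes was 69.7, 250 and 25.0 CPM. The 2 backgrounds differed by 2.40 times (1.80 to 3.22), more than the 1.48 above. A single source thus does not give a single value, and the measure is weaker than its intervals. It cannot decide whether free RNA made the Wnt excess of cluster 5. In the mutant-dominated clusters, the supposed source, the measure was 0.959 (0.944 to 0.974), below all 3 classes that follow but also below erythroid-like cells (2.68, 2.15 to 3.36). Against erythroid-like cells the value was 0.536 (0.399 to 0.711) in choroid plexus-like, 0.660 (0.481 to 0.910) in oligodendrocyte precursor-like and 1.05 (0.775 to 1.42) in granule cell precursor-like cells, while the measure itself was 1.44, 1.78 (1.44 to 2.20) and 2.84 (2.32 to 3.47) in these classes and 1.12 (0.925 to 1.34) in microglia-like cells. The last 2 classes thus lay above 1 background and not above the other. Free RNA stays open for all 3, as it does for cluster 5. A candidate explanation for cluster 5 is recombination in some of its cells, which was not tested.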

How the results depend on the processing

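No paired analysis was possible because each genotype was 1 pool of 3 samples. Of 147 alternative values 12 reversed the direction of a result; numbers of genes 2-fold apart and the mutant-dominated share have no direction to reverse. Alternatives chosen after the data were seen were haemoglobin left out of totals, mutant-dominated clusters left out (of the whole library, of the progenitor-like class, and of the denominator of GABAergic and PTF1A shares), cluster 5 alone, and list members kept in the clustering for progenitor-like medians and counts. Depth limits what can be said of genes below 10 CPM and of cells below 3000 UMIs. The cause of the moves below was not tested, unless named.

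With no cell filter the progenitor-like share ratio was 0.530, granule lineage 0.255, unipolar brush 0.341, PTF1A-lineage 2.17 (reversed: an added mutant cluster of 861 cells took the name, while the cluster with Ptf1a held 394 control and 7 mutant cells), the Wnt share difference 26.3 and the Mki67 or Top2a difference −9.39 points, the progenitor-like Wnt median 1.17, the G2/M median −0.13 (reversed) there and −0.66 in the whole library, progenitor-like genes 2-fold apart 190 and the mutant-dominated share 39.8%. With the stricter filter the progenitor-like ratio was 1.59 and its G2/M median −0.82 (both reversed), Wnt medians 3.22 (progenitor-like) and 2.50 (whole), progenitor-like genes 953 and the mutant-dominated share 58.9%. With doublets kept the progenitor-like ratio was 1.66 and its G2/M median −0.30 (both reversed), its Wnt median 3.04, genes 826, granule lineage 0.194 and the mutant-dominated share 54.8%.

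At Leiden resolution 0.5 the progenitor-like ratio was 0.545, its G2/M median −0.28 (reversed), Wnt median 0.95, genes 193 and the mutant-dominated share 54.9%. At resolution 2 these were 0.809, 0.14 and 1.96, with granule lineage 0.341 and a mutant-dominated share of 55.9%. With list members kept in the clustering the progenitor-like ratio was 1.72 and its G2/M median −0.94 (both reversed), its Wnt median 3.13, genes 962 and the mutant-dominated share 57.7%. With classes from control cells only, where each mutant cell must take a control class, the progenitor-like ratio was 1.23 and the PTF1A-lineage ratio 1.19 (both reversed), GABAergic interneuron 0.304, granule lineage 0.640, unipolar brush 0.563, and the progenitor-like medians 3.05 (Wnt) and 0.15 (G2/M) with 722 genes.

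Median-of-ratios scaling gave G2/M medians of −0.67 (whole) and 0.023 (progenitor-like). Means of per-cell CPM gave −0.72 and −0.16 (reversed) and a whole-library Wnt median of 2.34. A pseudocount of 10 gave whole-library medians of 1.45 (Wnt) and −0.50 (G2/M) with 329 genes, and a progenitor-like Wnt median of 1.90 with 232 genes; a pseudocount of 0.1 gave a whole-library Wnt median of 2.55. The 50 CPM filter left 282 genes (whole) and 182 (progenitor-like) 2-fold apart, and no low-count filter 823 (progenitor-like). Thinning to 1500 UMIs gave differences of 34.9 (Wnt) and −8.76 (Mki67 or Top2a) points, no thinning −13.3 for the latter, and 1 or 3 required Wnt UMIs 20.4 and 37.5. Cluster 5 alone gave 1.35 (Wnt), 0.29 (G2/M) and 123 genes. Without the mutant-dominated clusters the whole-library medians were 0.76 (Wnt) and −0.36 (G2/M) with 325 genes, the progenitor-like Wnt median 1.09 with 173 genes, and the ratios 0.0432 (GABAergic interneuron) and 0.0366 (PTF1A-lineage).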

Other observations

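Within the mutant-dominated clusters several kinds of cells were seen from their leading genes. Apart from the list member Notum, these were open to the clustering and so describe it. Cluster 6 was led by Neurog2, Olig3 and Shox2, cluster 13 by Lgr6 and Notum, clusters 0 and 39 had Fstl4 and Adamts19 in common, cluster 33 had Atoh1 and Barx2, and cluster 35 was led by histone genes of S phase. Cluster 3, with 1342 mutant and 130 control cells, had Tfap2d, Lhx9 and Sst among its leading genes, and 12.02% of its mutant cells had the Wnt readout. It held 12.2% of Xist-marked and 6.12% of Y-marked mutant cells, and 1.69% and 0.327% of control cells, so the size of its difference was not the same for the 2 marks, which stand for different embryos. Cluster 12, with 642 mutant and 250 control cells, had Pax7, Tal2 and Gata3, markers of midbrain or isthmic neurons, enriched. Gad2 and Pnoc were among its leading genes, and dissection as its source was not tested. Over every barcode the mutant to control ratio was 4.07 for Gad1 and 1.15 for Gad2. Clusters 10, 11 and 23, unnamed and with the granule precursor genes Mfap4 (cluster 11) or Cadps2 (cluster 23) among the leading genes of 2 of them, held 5.69%, 5.80% and 3.41% of control and 0.888%, 0.524% and 0.211% of mutant cells.

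Cell classes shared by both libraries differed in further genes. Some of these lead other cells, such as Fstl4 and Pcdh15 in the mutant-dominated clusters, Mfap4 in granule cell precursor-like and Ttr in choroid plexus-like cells, and were not separated from free RNA. In choroid plexus epithelium-like cells, histone genes of S phase were higher in the mutant library (Hist1h1b 96.9 against 17.8 CPM, Hist1h2ae 68.5 against 24.3 CPM), as was Pcdh15, while Nrxn3, Penk (91.8 against 229 CPM) and Robo2 were lower. In granule cell precursor-like cells Fbxo2, Trpm3 and Nts (100.8 against 26.1 CPM) were higher and Slc2a13, Dlgap1 and Fam155a lower. In differentiating granule neuron-like cells Nts (76.4 against 3.66 CPM), Nckap5 and Ptgds were higher and Sfrp1 (18.9 against 78.2 CPM), Plekhg1 and Mfap4 lower. In unipolar brush cell-like cells Fstl4, Pcdh15 and Csmd3 were higher and Mfap4, Opcml and Ppp1r14c lower. In fibroblast- or meninges-like cells Nppc (81.5 against 2.80 CPM), Mrln and Igfbp6 were higher and Asic2 (106 against 424 CPM), Erbb4 and Nav2 lower; mutant cells of this class included cluster 41. In pericyte- or mural-like cells Fstl4, with 3 control UMIs, had a ratio of 43.4 (14.5 to 213), with Mybpc1 and Lingo2, and Nrxn3, Hs3st5 and Nts were lower. In erythroid-like cells Ttr (334 against 139 CPM), Ptn and Ncf4 were higher and Dcc, Ckb and Npm1 lower.

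The first pattern weighed was the mutant-dominated clusters; of its tests, the one on non-neural classes was chosen after the result was seen. A single embryo as their source was argued against by their share of Xist-marked over Y-marked mutant cells, 1.03 (0.983 to 1.08). A difference touching every cell of the library stays open: the Wnt median was −0.032 (−0.11 to 0.07) in endothelial-, mural- and fibroblast-like cells, some with a high baseline, but 2.59 in microglia-like and 2.31 in erythroid-like cells. A candidate explanation is stabilised beta-catenin with loss of Smarca4 in the cre lineage. With no control that carried 1 of the 2 alleles, their parts cannot be separated here, and dissection of the 2 pools stays untested, including for the midbrain gene Tfap2d in cluster 3.

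The second pattern was the low number of PTF1A- and PAX2-lineage cells; the tests on dilution and on Ptf1a with Kirrel2 alone were chosen after the result was seen. On a single embryo as the cause, the larger ratio of the 2 sex-marked parts was 0.0294 (0.0117 to 0.0614). With 16 such mutant cells in all, both parts had to lie below the bound set. The split therefore could not decide, and shows only that these cells were few under both marks. Loss in filtering was argued against by the summed UMIs of Ptf1a, Pax2, Kirrel2, Slc6a5 and Gjd2 over every barcode, with a ratio of 0.136 (0.127 to 0.146). Pax2 (0.589 against 17.9 CPM) weighed most in this sum. Slc6a5 alone had a ratio of 0.116, but Gjd2 had 0.797 (0.665 to 0.954), so the sum speaks mainly for Pax2. Dilution by the mutant-dominated clusters was argued against by a summed class ratio of 0.0177 (0.0101 to 0.0289), against 0.438 for all cells outside them. The ratio of 0.0404 (0.0230 to 0.0660) without these clusters follows from those values and is no separate evidence. For Ptf1a and Kirrel2 alone the ratio was 0.284 (0.256 to 0.315), between the bounds set, with 79.8% of Ptf1a UMIs of kept mutant cells in mutant-dominated clusters. Cells lost to either step were argued against, since the cluster with Ptf1a held 394 control and 7 mutant cells with no cell filter, and the class ratio was 0.0268 with doublets kept; both steps left out together were not run. A candidate explanation is that such progenitors took another state, which these values leave untested.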
